A study of Mus musculus with 2 samples.

How the data were processed

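Small RNA of fewer than 30 nucleotides was sequenced from the livers of B6NCrl mouse embryos at embryonic day 11.5, per the labels, which name the assay microRNA-seq. Each of the 2 libraries came from a pool of embryos of both sexes. The labels call them biological replicates 1 and 2 and give a pool of 109 embryos for replicate 1, while the pool size for replicate 2 was not stated. Both libraries formed 1 group, so no comparison between groups existed and no covariate was fitted.

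The deposited files held whole-number counts of reads per microRNA gene, not normalised, in 3 columns: reads on either strand, reads on the strand of the gene and reads on the opposite strand. Alignment was to mouse assembly mm10 and counting used GENCODE annotation M4, per the deposited description of the files. The aligner, the counter and any adapter trimming were not given in the sources used here. Each file opened with 4 summary classes (unmapped, mapping to several places, no feature, ambiguous) that name no gene. These stayed out of library sizes and tests. The layout of the columns follows that of STAR gene counts, which was read from the files and not from a stated method.

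Replicate 1 held 12750572 reads and replicate 2 held 5471247. On the strand of the gene, 26.2% of the reads of replicate 1 (95% exact Clopper-Pearson binomial interval 26.2 to 26.3) and 29.0% of those of replicate 2 (28.9 to 29.0) were assigned to a microRNA gene. Reads mapping to several places made up 22.0% and 22.6%, unmapped reads 38.1% and 37.8%, and reads outside any counted gene 13.6% and 10.7%, in replicates 1 and 2. The ambiguous class held 0 reads in that column. A count of 0 allows up to 3 counts, which is 0.897 CPM (defined next) in replicate 1 and 1.89 CPM in replicate 2. Reads carried no molecular identifiers that the sources describe, so intervals and floors cover counting error only.

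Counts per 1000000 assigned counts (CPM) were computed here from the deposited counts, as the count on the strand of the gene over all assigned counts on that strand. Means are given with the SD over both libraries (n = 2). Gene names and coordinates came from GENCODE M21, which uses the same assembly, by matching Ensembl gene identifiers without their version. Of the 1973 counted genes, 1894 matched, 1815 of them with the same version, and the 79 without a match held 4 counts in both libraries together. Where a gene sat inside another gene was read from the M21 exons. Genes whose precursor shared at least 20 consecutive bases with another counted gene (907 genes, holding 7.38% and 9.23% of the counts in replicates 1 and 2) are uncertain, because reads that match both copies fall in the class mapping to several places.

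The count column, the tests, the gene lists, the rule for naming genes and the alternatives in the part on processing, apart from 2 named there, were chosen before the data were examined. The 16 lists comprised 9 of microRNAs known from a cell type or tissue and 7 of families or genomic clusters, written from textbook knowledge with older and newer symbols side by side. Of 204 symbols, 162 were names of counted genes. The named genes were the 10 with the highest mean CPM, the 2 most abundant detected members of each list, and up to 5 in each direction with the largest ratio between the libraries among called genes with a mean count of at least 100. A gene was detected when it had at least 10 counts in both libraries.

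Agreement between the libraries was measured across genes by Pearson's r and Spearman's rho of log2(CPM + 1), over genes with at least 10 counts summed over both libraries. The interval of r came from 1000 bootstrap draws of genes, and genes are not independent replicates. The common biological coefficient of variation (BCV) was estimated with edgeR 4.0.16 in R 4.3.3 (estimateDisp, intercept only, trimmed mean of M values, TMM, normalisation), with an interval from 100 bootstrap draws of genes. Each gene was tested between the libraries with a two-sided exact binomial test of its counts against the share given by the TMM effective library sizes, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold, with 0.5 added to each count for the log2 ratio. This test knows only counting noise and compares 2 libraries, not conditions. Each list with at least 3 tested genes was set against 10000 random lists of the same size matched on mean abundance. The random lists were drawn from all tested genes, members of the list included, which makes a shift of a large list harder to see. DESeq2 1.42.0 supplied size factors for an alternative. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

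The procedure was tested on simulated counts with the real gene means and library sizes. With counting noise only and 200 genes changed, 83.7% of the genes changed 4-fold and 89.6% of those changed 3-fold were called. At 2-fold 40.4% and at 1.5-fold 2.13% were called, against 0.377% of unchanged genes. With no gene changed, 3 of 458 genes were called at a simulated BCV of 0.1, 12 of 461 at 0.2 and 92 of 448 at 0.4. The BCV measured here, 0.260, lies between the last 2 settings, as do the 33 genes called between their counts, so a call shows a difference between these libraries beyond counting noise and no more. In a noisier simulation a list of 12 genes shifted by 1 on the log2 scale reached percentile 95.9 among random lists, so shifts of short lists can be missed.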

Results

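The microRNA content of the embryonic mouse liver was measured at day 11.5, when the organ is both a growing epithelium and a site of blood formation. Short RNAs from 2 pools of livers were sequenced, giving 3344673 reads assigned to microRNA genes in replicate 1 and 1584499 in replicate 2. The question the design holds is which microRNA genes the liver expresses at this stage, and how far separate pools differ. Of 1973 counted genes, 347 were detected with at least 10 counts in both libraries, 104 of them at 1000 CPM (counts per 1000000 assigned counts) or more in both, and 1249 had 0 counts in both. A count of 0 allows up to 0.897 CPM in replicate 1 and 1.89 CPM in replicate 2.

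Among assigned reads, the profile was led by the endothelial gene Mir126a, the proliferation-linked Mir17 and the imprinted Mir335. Reads mapping to several places were left out, so genes with near-identical copies can rank too low. Reads on the strand opposite to a counted gene were left out too. Without regard to strand, the locus of Mir142, a microRNA of blood cells, ranked 4. Reads there on the opposite strand averaged 37017 CPM, against 29570 CPM for Mir122 in that column. Mir20a was not among the 10 highest there. Mir126a (ENSMUSG00000065540.1) averaged 68747 ± 15986 CPM (SD, n = 2) and lies on chromosome 2 at 26591357 to 26591429 of mm10, in an exon of Egfl7, a gene expressed in endothelium. Mir17 (ENSMUSG00000065508.1) averaged 64155 ± 18563 CPM (SD, n = 2), from chromosome 14 at 115043671 to 115043754, in an exon of the host transcript Mir17hg. Mir335 (ENSMUSG00000065501.1) averaged 61861 ± 10391 CPM (SD, n = 2), from chromosome 6 at 30741299 to 30741396, in an intron of Mest, which is expressed from the paternal allele. The values of these 3 genes overlapped between libraries, so their order was not resolved. By mean, the hepatocyte gene Mir122 (ENSMUSG00000065402.1) followed with 32583 ± 2693 CPM (SD, n = 2). It lies on chromosome 18 at 65248861 to 65248926, in an exon of the long noncoding RNA AC157910.3. In replicate 1 Mir30e stood above Mir122, with 37299 against 30679 CPM, so the order of Mir122 and Mir30e was not resolved.

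The remaining 6 of the 10 most abundant genes lay between 23783 and 28542 CPM. Mir30e averaged 28542 ± 12383 CPM (SD, n = 2) and sits in an intron of Nfyc, on chromosome 4 at 120772606 to 120772697. Mir99a averaged 27571 ± 4670 CPM in an intron of Mir99ahg, on chromosome 16 at 77598936 to 77599000. Mir322 averaged 27512 ± 6765 CPM, on chromosome X at 53054255 to 53054349, with no other gene over it. Mir21a averaged 25896 ± 4854 CPM in an exon of Vmp1, on chromosome 11 at 86584067 to 86584158. Mir130a averaged 24623 ± 1957 CPM, on chromosome 2 at 84741115 to 84741178, outside other genes. Mir20a averaged 23783 ± 7709 CPM in Mir17hg, on chromosome 14 at 115044157 to 115044263. Together the 10 genes held 38.5 ± 2.18% of the counts (SD, n = 2), and the 16 most abundant genes held 50% or more. Consecutive means among these 6 differed by less than the SD of either gene.

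**Figure D1:**
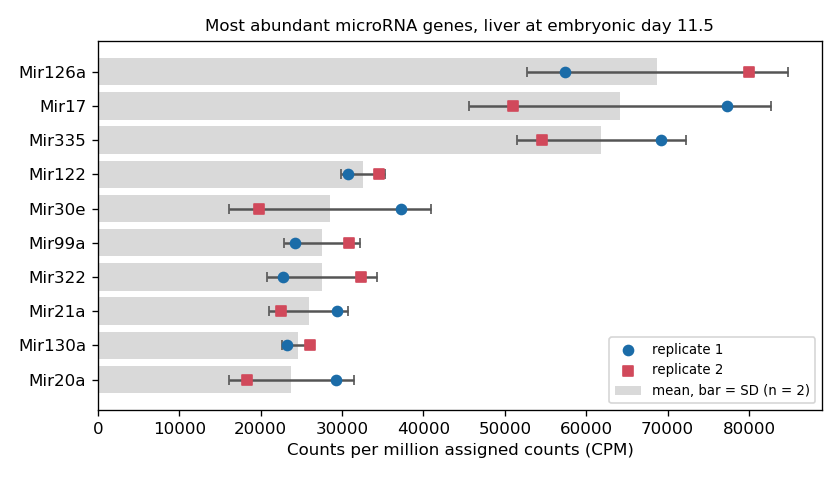
CPM of the 10 most abundant microRNA genes in embryonic liver, counted on the strand of the gene and without reads mapping to several places. Grey bars give the mean of both libraries with the SD (n = 2), circles replicate 1 and squares replicate 2. The lowest single value for Mir126a, Mir17 and Mir335 is 51029 CPM, for Mir17 in replicate 2.

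Among lists of cell-type microRNAs counted on the strand of the gene, the endothelial gene Mir126a and the hepatocyte and mesenchymal lists held the most counts. The place of the leukocyte list is uncertain, as given below. Shares of counts from whole livers do not show which cells held the RNA, and a list names only the cell type its microRNAs are known from. Mir126a, the 1 counted gene of the endothelial list, made up 6.87 ± 1.60% of the counts (SD, n = 2). Hepatocyte microRNAs took 3.64 ± 0.235% of the counts (SD, n = 2), with 4 of 6 genes detected. Most of it was Mir122, the leading microRNA of the mature liver, while Mir148a, which is also abundant in adult liver, averaged 1475 ± 353 CPM. The mesenchymal and smooth muscle list held 3.16 ± 0.804%, with 7 of 8 genes detected, led by Mir143 at 17534 ± 8573 CPM and by Mir214 at 9346 ± 798 CPM (SD, n = 2). Mir214 lies in an exon of Dnm3os, which runs antisense to Dnm3. In counted reads, each of these lists stood far above the markers of striated muscle and brain, whose low counts are uncertain, as given below.

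Blood cell microRNAs were present at close to 1% for each of 2 lists on the strand of the gene. The erythroid list held 0.984 ± 0.214% of the counts with 3 of 3 genes detected (SD, n = 2). It was led by Mir451a, which matures in red cell precursors without Dicer, at 8644 ± 1625 CPM, and Mir144 from the same cluster averaged 837 ± 533 CPM. The leukocyte list held 0.938 ± 0.165% with 5 of 6 genes detected. Its leading genes were the myeloid Mir223, at 5010 ± 108 CPM, and Mir342, in an intron of Evl, at 3948 ± 1597 CPM (SD, n = 2). The ranges of these shares over both libraries overlapped. The miR-181 family, known from lymphocyte development, held 0.928 ± 0.189% with 6 of 6 genes detected. It was led by Mir181d at 3877 ± 1221 CPM and Mir181c at 3784 ± 534 CPM in an intron of Nanos3. Neither of these genes shares at least 20 bases with another counted gene. Any family member that does can be counted too low, so the leading genes and the share of this family are uncertain. Reads at the Mir142 locus fell on the strand opposite to the counted gene and are not part of the leukocyte share. Without regard to strand, a count chosen after the data were seen, the leukocyte list held 0.852 ± 0.155% without this locus and 4.55 ± 0.328% with it (SD, n = 2), against 3.31 ± 0.195% for the hepatocyte list and 2.87 ± 0.714% for the mesenchymal list.

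Markers of striated muscle and brain were low. Striated muscle microRNAs held 0.0845 ± 0.00598% of the counts with 5 of 9 genes detected, led by Mir208b at 328 ± 4.44 CPM and Mir208a at 214 ± 81.1 CPM, which lie in introns of the cardiac myosin genes Myh7 and Myh6. Neural microRNAs held 0.0495 ± 0.00895% with 8 of 15 genes detected. The most abundant were Mir128-1 at 123 ± 9.64 CPM and Mir138-2 at 109 ± 53.0 CPM (SD, n = 2). Their order turned between the libraries: Mir128-1 had 130 and 116 CPM and Mir138-2 146 and 71.3 CPM in replicates 1 and 2. All 7 undetected neural genes and 2 of the 4 undetected striated muscle genes share at least 20 bases with another counted gene, as do both named neural genes, so low counts of these lists are uncertain. The pancreas and gut list held 0.219 ± 0.0378% with 2 of 5 genes detected, nearly all of it from Mir375, known from pancreatic islets, at 2161 ± 381 CPM. Mir217 of that list averaged 18.0 ± 4.09 CPM. Epithelial microRNAs held 0.582 ± 0.00129% with 7 of 7 genes detected, led by Mir429 at 1776 ± 286 CPM and Mir200c at 1453 ± 270 CPM, both of the family that represses Zeb transcription factors.

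**Figure D2:**
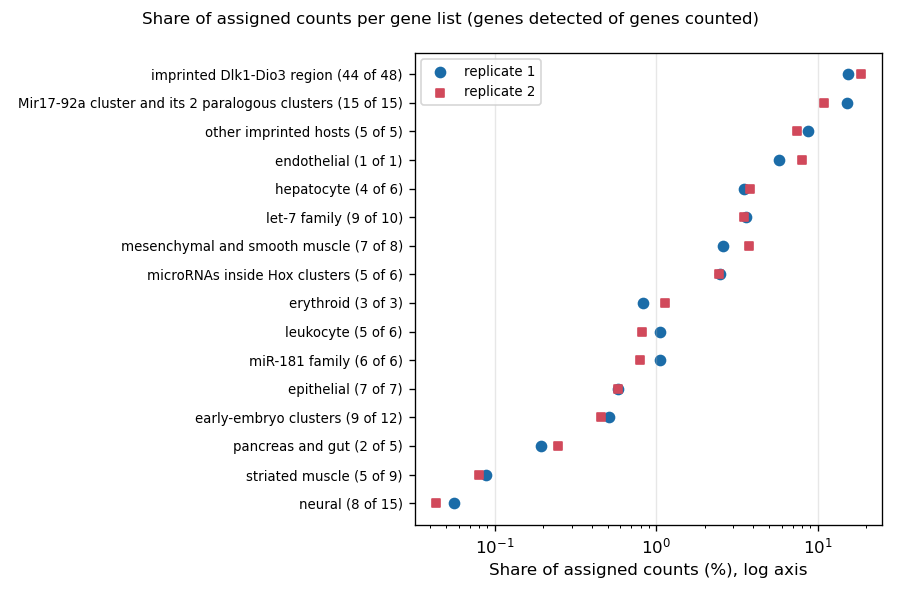
Share of assigned counts, in percent on a log axis, held by each gene list in replicate 1 (circles) and replicate 2 (squares). The Dlk1-Dio3 region holds 15.4% and 18.5% and the neural list 0.0558% and 0.0432%.

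The largest shares of the counts belonged to genomic clusters. The imprinted Dlk1-Dio3 region on chromosome 12, whose microRNAs are expressed from the maternal allele, held 16.9 ± 2.19% of the counts (SD, n = 2), with 44 of 48 genes detected between positions 109563692 and 109747960. On the strand of the gene, its highest means were those of Mir411 at 18929 ± 9783 CPM and Mir487b at 18168 ± 1586 CPM (SD, n = 2), but Mir411 had 12012 CPM in replicate 1 and 25847 CPM in replicate 2, so it led in replicate 2 only. In replicate 1 it lay below Mir487b and below Mir541 and Mir127, both named here after their values were seen. Mir411 shares at least 20 bases with another counted gene. The Mir17 cluster and its paralogous clusters, which promote proliferation, held 13.1 ± 3.08% with 15 of 15 genes detected. Mir92-1 of these clusters shares at least 20 bases with another counted gene, so this share can be too low. The list named other imprinted hosts held 8.09 ± 0.914% with 5 of 5 genes detected. After Mir335 the most abundant was Mir298, at 7915 ± 186 CPM, over which M21 has no other gene.

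**Figure D3:**
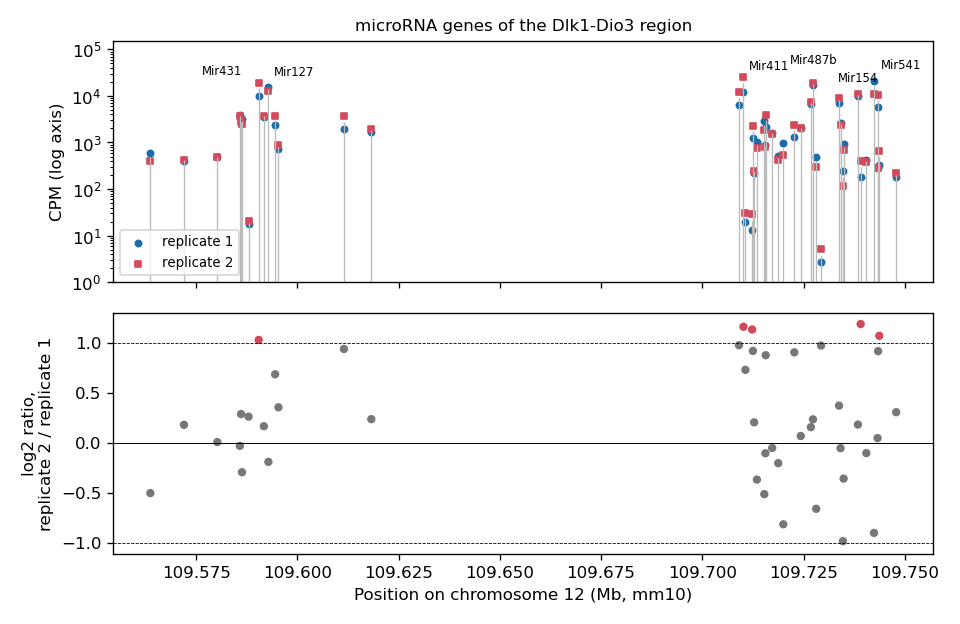
MicroRNA genes of the Dlk1-Dio3 region with at least 10 summed counts, by position on chromosome 12 (Mb, mm10). The upper panel gives CPM on a log axis in replicate 1 (circles) and replicate 2 (squares), with the 6 most abundant genes named, and the lower panel the log2 ratio of replicate 2 over replicate 1, with called genes in red. Ratios run from -0.98 to 1.19.

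The let-7 family, whose precursors are held back by Lin28 in early embryos, was already present at 3.53 ± 0.0587% of the counts with 9 of 10 genes detected. The undetected gene shares at least 20 bases with another counted gene. Reads that match several copies were not counted, so the share of the family can be too low. Mirlet7g averaged 21060 ± 696 CPM, in an intron of Wdr82, and Mirlet7i 9422 ± 93.0 CPM (SD, n = 2). MicroRNAs inside the Hox clusters held 2.47 ± 0.0179% with 5 of 6 detected, led by Mir10a at 16146 ± 419 CPM and Mir10b at 5716 ± 464 CPM, the latter in introns of Hoxd3 and Hoxd4. Clusters known from pluripotent cells held 0.482 ± 0.0430% with 9 of 12 detected, led by Mir302d at 1533 ± 321 CPM and Mir302a at 1517 ± 35.1 CPM. Mir302a shares at least 20 bases with another counted gene. All 16 lists together held 62.0 ± 0.590% of the counts (SD, n = 2).

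The pools gave nearly the same order of genes, while single genes often differed by more than read counting alone gives. Among 257 genes with a mean count of at least 100, 243 (94.6%) lay within 2-fold of each other and the median fold was 1.28. Across the 454 genes with at least 10 summed counts, Pearson's r of log2(CPM + 1) was 0.986 (bootstrap interval 0.983 to 0.988) and Spearman's rho 0.977; genes are not independent replicates. The common biological coefficient of variation was 0.260 (bootstrap interval 0.245 to 0.282), which covers biological and technical spread between the pools alike.

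Of the 454 genes, 33 were called at least 2-fold apart, 22 higher in replicate 2 and 11 higher in replicate 1. Scaling by total assigned counts gave 19 and 15. The 5 named genes higher in replicate 2 were Mir33, in an intron of the cholesterol regulator Srebf2, with a log2 ratio of 1.54, the erythroid Mir144 with 1.46, Mir496a in an intron of Mirg with 1.19, Mir411 with 1.17 and Mir700 in an exon of Rcan3 with 1.13. Mir144 stood at 460 CPM in replicate 1 and 1214 CPM in replicate 2. The smooth muscle gene Mir143 was also called, with a log2 ratio of 1.10. Only 3 genes qualified in the other direction: Mir5113 in an exon of Tnrc6b with -1.54, Mir362 in an intron of Clcn5 with -1.16, and Mir702 in an exon of Plod3 with -1.02. The exact binomial test, with Benjamini-Hochberg adjustment, gave adjusted p-values from 7.64e-191 for Mir144 to 7.03e-08 for Mir702 among the called genes named above for which a p above 0 could be computed. The test compares these libraries, not conditions, and when edgeR's exact test was run with an assumed biological coefficient of variation of 0.2, 1 gene was called. This was Mir6538, with 14 and 46 counts and a log2 ratio of 2.82, named here after its value was seen.

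No list stood apart between the libraries: 0 of 15 lists had a median log2 ratio outside the central 95% of random lists matched on abundance. The Dlk1-Dio3 region came nearest, with a median of 0.1875 at percentile 97.0, just under the upper limit of 0.1882. Its own genes were among those the random lists were drawn from, so a shift of this region is not excluded. Of its 45 tested genes, 5 were called, all higher in replicate 2. The leukocyte list lay at percentile 4.77 with a median of -0.52 and 0 of 5 genes called. The hepatocyte list had a median of -0.37 at percentile 10.5 and the erythroid list 0.45 at percentile 92.3. Medians of the remaining 11 lists ran from -0.39 for the miR-181 family, at percentile 6.32, to 0.24 for striated muscle, at percentile 81.3.

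**Figure D4:**
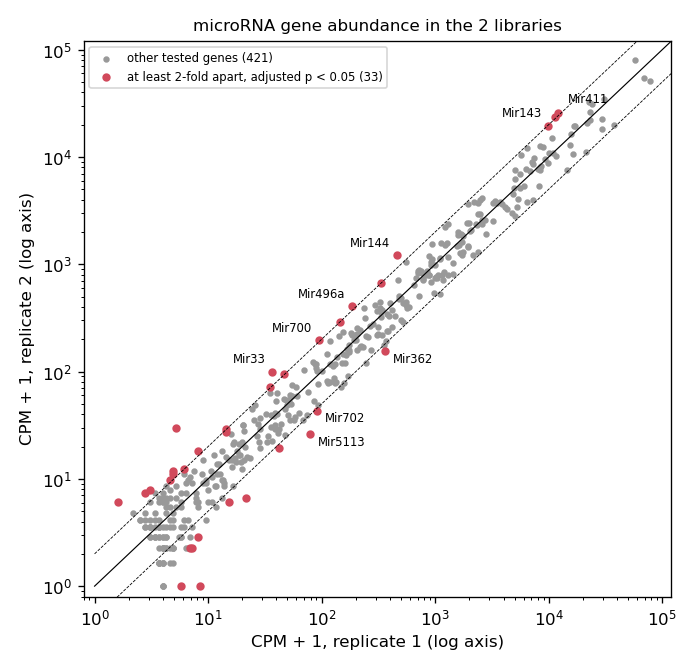
CPM + 1 of the 454 tested microRNA genes in replicate 1 and replicate 2, on log axes. Dashed lines mark 2-fold differences before TMM scaling and red points the 33 called genes, of which the 9 chosen by the naming rule are labelled. Mir6538 is not labelled.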

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

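The tests in this part were all chosen after the counts had been seen, and no biological explanation was tested. Reads on the strand opposite to a counted gene, a column outside the main measurement, rose above what a count of 0 allows at 10 genes that had few or 0 reads on their own strand. The opposite strand held 325639 reads in replicate 1 and 167891 in replicate 2, which is 8.87% and 9.58% of all reads counted without regard to strand.

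The largest part of this signal came from the locus of Mir142, a microRNA of blood cells. The counted gene there is Mir142b, on chromosome 11 at 87756841 to 87756955, with 2 and 3 reads on its own strand against 140377 and 62714 on the other. Those reads averaged 37017 CPM of all unstranded counts, rank 4 among all genes in that column. On chromosome 12, in the Dlk1-Dio3 region, opposite-strand reads averaged 21593 CPM at Gm24321, which lies across from Mir409, 9638.5 CPM at Gm25252, across from Mir376a, 4697 CPM at Mir299b, across from Mir299a, and 2469 CPM at Gm25750, across from Mir380. Elsewhere the values were 6929 CPM at Gm25301 (across from Mir378a), 6253 CPM at Gm24083 (Mir191), 3096 CPM at Gm25927 (Mirlet7e), 381 CPM at Mir497b (Mir497) and 41.9 CPM at Gm24111 (Mirlet7f-1).

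Loss of strand during library making was excluded, because the median opposite-strand share at the 100 most abundant genes was 0%, with 88 of them at 0 and a highest share of 0.866%. A candidate explanation is that the annotation used for counting held only the other strand of an expressed locus. Of the opposite-strand counts, 99.97% lay at genes over which the later M21 annotation has a microRNA gene on the opposite strand, while 1.69% of all matched genes have one. Counted without regard to strand, the ambiguous class held 2 reads in replicate 1 and 0 in replicate 2. Under the column layout read from the files, reads over counted genes on both strands would fall in that class. These values argue against the M21 partners having been among the counted genes. The M4 annotation itself was not used here, so what else it lists at these loci stays open. If these reads belong to the M21 partners, the leukocyte, Dlk1-Dio3 and let-7 shares in the report leave them out. Counting without regard to strand, adding those loci took the leukocyte list from 0.852 to 4.55% of counts, 5.35 times as much, the Dlk1-Dio3 region from 15.8 to 19.2% and the let-7 family from 3.21 to 3.52%.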

How the results depend on the processing

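The unstranded column for the share of assigned reads and the addition of opposite-strand loci to 3 list shares were chosen after seeing the data, and the others before. The latter changed both the column and the loci: the leukocyte share went from 0.938% to 0.852% with the unstranded column and 4.55% with the loci added, the Dlk1-Dio3 share from 16.9% to 15.8% and 19.2%, and the let-7 share from 3.53% to 3.21% and 3.52%. No paired analysis was possible because there was only 1 group. Counting both strands moved the assigned share from 27.6% to 30.4% and the share of all 16 lists from 62.0% to 56.8%, since the opposite-strand reads joined the total. Leaving Mir126a out of the denominator raised the latter to 66.6%, by construction. Requiring 1 count in both libraries in place of 10 gave 575 detected genes. Pearson's r was 0.976 with a pseudocount of 0.1 CPM, 0.992 with no filter (1973 genes, most at 0 in both libraries), where Spearman's rho fell from 0.977 to 0.905, and 0.983 from 100 summed counts, with a rho of 0.983; the cause was not tested. Called genes fell from 33 to 1 under edgeR's exact test at an assumed BCV of 0.2, which adds spread between libraries that the binomial test leaves out, and all 9 named called genes lost their call there. With 4 other alternatives the count ran from 32 to 35 and the 9 were called in each. Without a filter the split was 24 higher in replicate 2 and 8 higher in replicate 1. The BCV ran from 0.248 to 0.264. With the unstranded column, 0 of 15 lists stood apart. Total assigned counts and DESeq2 size factors gave 0 of 15 too, but could hardly have given another result. A change of scaling shifts the log2 ratios of all genes by the same amount, in the list and in the random lists alike.

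Without replicate 1 or replicate 2 the detected genes numbered 350 to 416, the top 10 share was 37.0 to 40.1%, Mir126a 57443 to 80051 CPM and the share of all lists 61.6 to 62.4%. With 1 library left, r, the BCV and the calls could not be computed. Of 41 other named genes, 13 moved by more than their SD with the unstranded column and 7 without Mir126a in the denominator. With TMM, 0 did. For these genes both changes acted almost only through the denominator, which all genes share. Which of them moved depended mostly on how small their SD was. Of 16 list shares, 6 moved with the unstranded column and 5 without Mir126a in the denominator. Replicate 1 was 2.11 times deeper, and thinning it to the depth of replicate 2 gave 333 detected genes.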

Other observations

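The groups in the next paragraph and the tests in this part were chosen after the values were seen, except the test of GC content, which was written before its result was seen. Sequences of mature microRNAs used for the length test were written from general knowledge after the ratios had been seen. Each was found in its M21 precursor, but its ends and the choice of arm could not be checked against the files, and 6 of the 60 genes had no sequence written.

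Several families outside the lists were abundant. The Mir99 and Mir100 family held 5.19 ± 0.738% of the counts (SD, n = 2), from 3 genes, Mir99a, Mir99b and Mir100. The Mir30 family held 4.55 ± 1.95% from 6 detected genes, with 5.92% in replicate 1 and 3.17% in replicate 2. The cluster of Mir322, Mir351, Mir503 and 4 other genes on chromosome X held 3.51 ± 0.519%, and the Mir130 and Mir301 family 3.44 ± 0.0737%. The genes of Mir15 and Mir16, which restrain the cell cycle, held 1.68 ± 0.0132%.

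Differences between the libraries were spread over single genes, and some genes made from the same primary transcript differed. Mir143 had a log2 ratio of 1.10 and its partner Mir145a 0.07, while Mir144 had 1.46 and Mir451a 0.45. Mir192 had 0.81 where Mir194-2, which shares 20 bases with another counted gene, had -0.74. These pairs are examples, and other partners moved alike, such as Mir17 with -0.54 and Mir20a with -0.61 in Mir17hg. The SD of log2 ratios over 187 genes was 10.04 times the SD from sampling of reads. This ratio argues against sampling of reads as the main cause for these 187 genes. Genes with fewer counts were not covered, and the ratio does not separate biological from technical spread. GC content of the precursor as the cause was argued against by a Spearman rho of -0.00689 across 285 genes (bootstrap interval -0.126 to 0.104, two-sided permutation p = 0.908). A shift of whole loci, from another mix of cells or other transcription, was argued against as the main cause, because neighbours within 10 kb differed 1.07 times as much as shuffled genes (bootstrap interval 0.881 to 1.25, 100 pairs, one-sided permutation p = 0.721). A candidate explanation is the length of the mature RNA, as a difference in size selection would give: across 54 of the 60 most abundant genes without a shared stretch of 20 bases, log2 ratio and length had a Spearman rho of -0.700 (bootstrap interval -0.816 to -0.546, Pearson's r -0.70, two-sided permutation p = 1e-05, the smallest 100000 permutations can give). The idea came from the ratios of 31 genes, 15 of them in this set. Without those 15, Spearman's rho was -0.56 across 39 genes (bootstrap interval -0.73 to -0.309, two-sided permutation p = 0.00012). Length remains a hypothesis found in the same data. The neighbour test covered genes within 10 kb of another only. A shift at loci of single genes, a shift as a lesser cause, and other differences between the pools of embryos stay open and untested.

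By length, the median log2 ratio was 0.64 for 10 genes of 21 bases or fewer (range 0.02 to 1.10), 0.18 for 30 genes of 22 bases (-0.86 to 0.69) and -0.55 for 14 genes of 23 bases or more (-0.90 to 0.11). The ranges overlap, and Mir30a with -0.86, Mir30e with -0.85 and Mir30d with -0.80, all of 22 bases, go against length as the only cause. Genes are not independent replicates.

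Genes with a near-identical copy were counted low. Within the lists, 45 genes sharing at least 20 bases with another counted gene had a median of 39.4 CPM and 117 others 836 CPM, a ratio of 20.7 on CPM + 1 (one-sided permutation within lists, p = 0.0011). This is consistent with reads of such copies having gone to the class mapping to several places, but lower expression of those genes was not tested.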
